A study of Homo sapiens with 12 samples.

How the data were processed

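The samples were tumours grown from MDA-MB-231, an established line of triple-negative breast cancer cells, in the mammary fat pad of mice. Per the labels, cells in 50 µl of Matrigel were injected into each of 10 mice per group, and treatment began at a tumour volume of 100 mm3. Mice received intraperitoneal injections on 5 days a week. The control group received the vehicle, made of 4% DMSO, 30% PEG300 and 5% Tween 80. The p38i group received SB202190, an inhibitor of the p38 MAP kinases, at 1 mg/kg/day. The EZH2i group received EPZ-6438 (tazemetostat), an inhibitor of the histone methyltransferase EZH2, at 10 mg/kg/day, and the combination group received both compounds. The labels write the code of the EZH2 inhibitor in 2 ways, and the duration of treatment is not stated. RNA from 3 tumours per group was sequenced, which gave 12 libraries.

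Per the labels' protocols, 1.3 µg of total RNA went into each library. The protocol names both a SMARTer mRNA kit and QuantSeq, a kit that reads the 3' ends of transcripts, so which of them made the libraries stays open. Per the labels, reads were trimmed with Trim Galore 0.5.0 and aligned with STAR 2.6.0 to hg19. The counting program, its annotation and its use of strand are not recorded, and neither is a removal of mouse reads. The deposited values are raw counts, 1 column per library and 1 line per gene symbol. The values are whole numbers, and no scaling is recorded in the file headers. The table held 25369 gene symbols. A further 3 lines named no gene, held 0 counts and were left out. No genome or annotation of hg19 was at hand, so no coordinates are given, and genes are named by the symbols in the file.

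Columns were joined to samples through the column number in each sample's description, read as the name in the header. For 2 of the p38i libraries this join failed, because the labels give column 5 to 2 p38i samples and column 6 to no sample. Column 5 was taken as a p38i library because both samples that name it are p38i. Column 6 was taken as one by elimination, since the design has 3 libraries per group. These libraries are called col5 and col6 below. The other libraries carry the tumour numbers of their titles, such as control 1-1.

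Genes were filtered with filterByExpr of edgeR 4.0.16 (R 4.3.3), which kept 12514 genes, and libraries were scaled by the trimmed mean of M values (TMM). A single quasi-likelihood model with 1 term per group was fitted to all 12 libraries with edgeR's robust option. Two-sided quasi-likelihood F tests compared p38i, EZH2i and the combination with the control, the combination with each single agent, and the combination minus both single agents plus the control, which is the interaction on the log2 scale. P values were adjusted by the Benjamini-Hochberg method over the 12514 genes, with a threshold of 0.05. Every adjusted p of a gene in the report comes from this edgeR fit. Standard errors of log2 fold changes were derived from the F statistics. Levels are CPM, counts scaled to TMM-scaled library sizes by the cpm function of edgeR, given as mean ± SD with n = 3 per group.

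The biological coefficient of variation was 0.219. The same code was tested on simulated counts for p38i against control, drawn from the real means and library sizes, with 50 genes changed at each of 4 sizes among 12322 genes. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery of genes at lower levels was not tested. These are the results of the edgeR fit. It recovered 0% of the genes changed by 0.5 on the log2 scale, 50% of those changed by 1, 80% of those changed by 1.5 and 88% of those changed by 2. Of its 114 calls, 5 were false. On the same simulated counts, the comparison of EZH2i with control, in which no gene was changed, gave 2 calls. On the same simulated counts limma-voom made 110 calls with 5 false ones, and DESeq2 made 135 with 16 false ones.

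A set of 35 gene lists was written down before the data were examined, together with the comparisons, the tests, the rule for named genes and the alternatives, except where the text says otherwise. They cover PRC2 subunits, genes reported in other systems to be repressed by EZH2, p38 pathway components, p38-responsive cytokine and AU-rich-element (ARE) transcripts, immediate early, mesenchymal and epithelial genes, and invasion proteases with their inhibitors. Further lists cover G2/M genes, S phase and E2F genes, cell cycle inhibitors with p53 targets, apoptosis, type I interferon response, antigen presentation, hypoxia, the unfolded protein and integrated stress response, cholesterol synthesis, the Notch pathway, breast stem cell associated genes, NF-kB targets and oxidative phosphorylation. Technical lists hold cytosolic ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, heat shock and housekeeping genes. Lists for other cell types hold markers of fibroblasts, macrophages, neutrophils, endothelium, pericytes, erythroid cells, adipocytes, skeletal muscle, and keratinocytes with luminal mammary cells.

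The 30 lists with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the 30 lists. Beside it, camera was run with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance without setting them against other genes. Members past the threshold were also counted with p values adjusted over the list alone.

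The named genes follow a fixed rule. For each comparison with control they are EZH2, MAPK14 and MAPK11. They are also, among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between groups, the 12 with the largest and the 12 with the smallest log2 fold change. The other comparisons used 5 in place of 12, and where no gene passed, the 5 per direction with the smallest p. Up to 4 members with the smallest p were named for each list. Gene models without a named function were passed over, and some genes that the rule names are not reported here.

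Alternatives used DESeq2 1.42.0, DESeq2 size factors in edgeR, upper quartile scaling, library totals alone, no filter, a mean of at least 5 CPM, limma-voom with and without the leading number of the tumour title as a random effect (col5 and col6, whose number is unknown, each had a level of their own), and only the compared groups. Further alternatives used a covariate for host cells, the data without genes of the other cell types, and each library left out in turn. The host covariate was the mean log2 CPM of 27 fibroblast, macrophage and endothelial markers. Offsets for GC content and transcript length (11761 of the 12514 genes, 94%, had a value from a GENCODE annotation), pairs of libraries left out, and a contrast of the mean of the 3 treated groups with the control were chosen after seeing the data. Comparisons that share the control libraries were set against 30 simulations of unchanged groups, in which the control libraries were simulated too. The 10 splits of each pair of groups, and 100 random regroupings of the 12 libraries, were refitted.

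Library totals ran from 2208771 to 4467942 counts. The limit that a count of 0 allows, taken as 3 counts, therefore lay between 0.671 and 1.36 CPM per library. These limits cover counting error only, since no molecular identifiers are recorded. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.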

Results

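RNA was sequenced from 12 tumours grown from MDA-MB-231 cells in mice, 3 from each of 4 groups. The groups were vehicle control, p38i (the p38 inhibitor SB202190), EZH2i (the EZH2 inhibitor EPZ-6438) and the combination of both. Each value is a count of reads per gene in 1 tumour. Library totals ran from 2208771 counts in EZH2i 6-1 to 4467942 in combination 9-1, and between 16389 and 17549 genes had at least 1 count in a library. The title of the series concerns EZH2 phosphorylation and p38 signalling in breast cancer progression. The comparisons ask what each inhibitor changes alone, what both change together, and whether one alters the effect of the other.

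Libraries of different groups resembled each other nearly as much as libraries of 1 group. Spearman correlations of log2 CPM, across genes, ran from 0.939 to 0.979 within groups and from 0.914 to 0.976 between groups. Component 1 of the 500 most variable genes held 32.6% of their variance and set control 1-1 (score -34.2) and control 1-3 (-18.9) apart, while control 2-1 (3.3) lay among the treated libraries. MALAT1, a nuclear non-coding RNA, took a larger share of the counts in each control than in each treated library. Its share ran from 3.12% in control 2-1 (95% Wilson interval 3.1 to 3.14) to 3.88% in control 1-1 (3.86 to 3.91). These intervals treat reads as independent and cover counting error only, not the spread between tumours. Among treated libraries it ran from 1.47% in EZH2i 5-4 (1.46 to 1.48) to 2.82% in EZH2i 6-1 (2.8 to 2.84). The tumour p38i col6 carried skeletal muscle transcripts, for which 11 of 12 markers were highest in this library. These markers made up 0.217% of its counts (0.213 to 0.222), against 0.00635% in EZH2i 5-4 (0.00561 to 0.00717) and 0.0238% in control 1-1 (0.0219 to 0.0258), the lowest and highest of the other libraries.

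**Figure D1:**
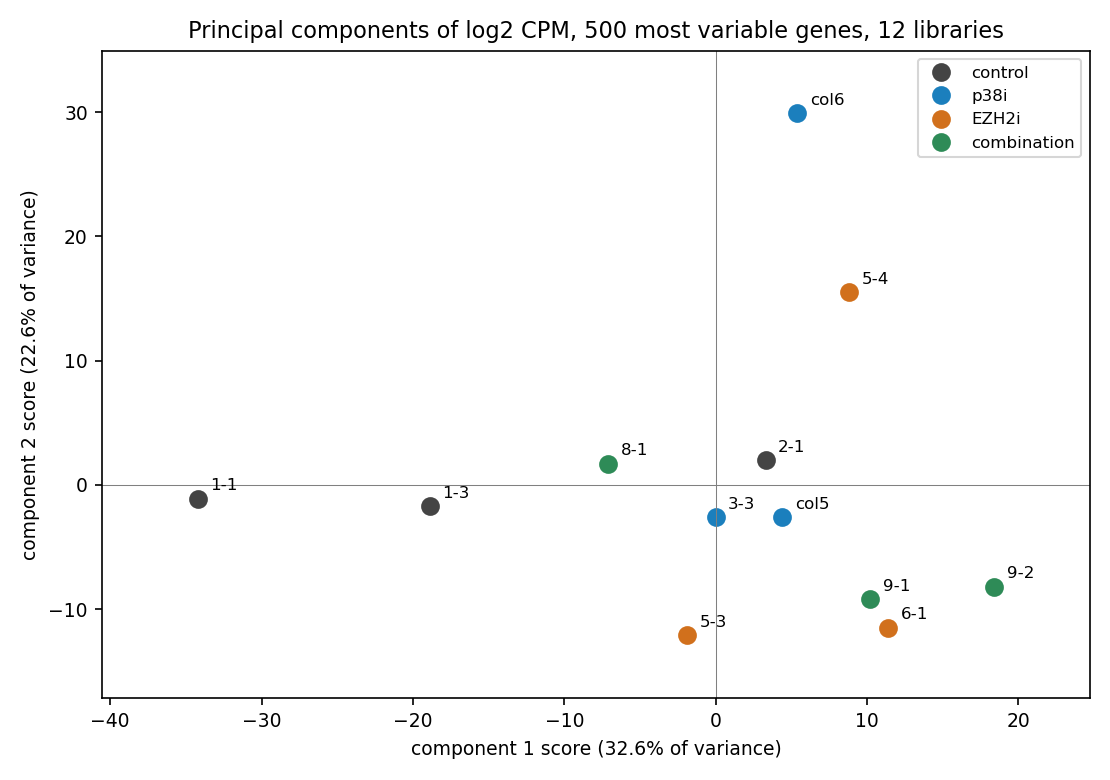
Scores of the 12 libraries on components 1 (32.6% of variance) and 2 (22.6%) of log2 CPM of the 500 most variable genes, with 1 point per library coloured by group and marked with its tumour number or column. Control 1-1 and control 1-3 lie at -34.2 and -18.9 on component 1, and p38i col6 lies at 29.9 on component 2.

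Both inhibitors act on proteins, so transcripts of their targets check no label. EZH2 measured 128 ± 27.3 CPM in control, 171 ± 42.8 in p38i, 153 ± 7.92 in EZH2i and 139 ± 21.1 in combination tumours (mean ± SD, n = 3). MAPK14, which encodes p38 alpha, measured 94.6 ± 1.68, 130 ± 9.6, 116 ± 27.4 and 121 ± 19.6 CPM in the same order. Neither passed in a comparison with control. With p38i the edgeR adjusted p was 0.283 for EZH2 and 0.185 for MAPK14, with EZH2i 0.571 and 0.461, and with the combination 0.808 and 0.328. MAPK11 had 0 to 10 counts per library and was too low to test.

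With p38 inhibition alone, 82 genes rose and 139 fell among the 12514 tested. With library totals alone as the scaling these were 102 and 102, and with DESeq2 280 and 337, so the excess of falls was absent under the first of these. ITGA10, a collagen-binding integrin subunit, fell from 267 ± 42.6 to 73.1 ± 5.5 CPM (mean ± SD, n = 3), by 1.87 on the log2 scale. ID1 and ID3, which block basic helix-loop-helix transcription factors, fell from 220 ± 47.1 to 34.8 ± 7.4 CPM and from 355 ± 113 to 56.1 ± 24.8 CPM. CXCR4, the receptor of the chemokine CXCL12, rose from 64.5 ± 4.35 to 193 ± 13.9 CPM. ADTRP, a membrane protein that regulates tissue factor pathway inhibitor, rose from 50.7 ± 19.1 to 182 ± 31.1 CPM.

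The largest falls with p38i were in ATOH8, a helix-loop-helix transcription factor (17.5 ± 5.14 CPM in control and 1.33 ± 1.38 in p38i tumours; log2 -3.62, SE 0.711, edgeR adjusted p = 0.031), and in 2 secreted serpins. SERPINA5 was 10.5-fold lower (adjusted p = 0.0239) and SERPINA3 8.42-fold lower (adjusted p = 0.0142). IFITM10 fell by 3.04, the DNA repair gene MGMT by 2.92 and GLIPR1L2 by 2.78 on the log2 scale. ID1 (SE 0.472) and ID3 (SE 0.522) each fell by 2.66. PAPLN fell by 2.56, the muscarinic receptor gene CHRM3 by 2.50 and SNED1 by 2.49. Adjusted p values of these 8 genes lay between 0.0164 and 0.0493. ITGA10 had the smallest adjusted p of the comparison, 0.000689.

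The largest rises with p38i included the endothelial receptor gene TIE1, at 5.32 ± 2.06 CPM against 0.437 ± 0.383 in controls, where each library held 0 to 3 counts. The ubiquitin ligase gene MARCH4 rose 6.51-fold (log2 2.70, SE 0.584). The proton pump subunit gene ATP6V0D2 rose 3.78-fold, ESM1, which encodes a secreted proteoglycan, 3.63-fold, and ADTRP 3.57-fold. The mitotic genes SKA1 and KIFC1 rose 3.34-fold and 3.28-fold. CTH, a cysteine synthesis gene, and the transcription factor gene GATA6 each rose 3.32-fold. C15orf48 rose 3.01-fold, CXCR4 3-fold (SE 0.261 on the log2 scale, adjusted p = 0.0164) and FBXO27 2.92-fold. The 12 genes had edgeR adjusted p values between 0.0164 and 0.0469, and in each, as the rule for naming demands, the 3 p38i libraries lay above the 3 controls.

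Proliferation genes were higher with p38i as lists. All 23 G2/M genes had a positive log2 fold change (median 0.68), and camera called the list higher (adjusted p = 7.32e-10). That call was lost with an estimated correlation (adjusted p = 0.684). The low level lay in control 1-1 and 1-3, whose median log2 CPM over the list was 5.44 and 5.8, while control 2-1 (6.44) lay within the p38i libraries (6.38 to 7.05). BUB1 passed over all genes (log2 1.18), and 18 members rose when adjusted over the list alone, among them CCNB2 (0.94), UBE2C (0.86) and CDC20 (1.03). All 20 S phase and E2F genes were positive (median 0.46, camera adjusted p = 1.63e-05; adjusted p = 0.684 with an estimated correlation). Their median log2 CPM was 4.26, 4.69 and 4.97 in control 1-1, 1-3 and 2-1, and 4.79 to 5.28 in p38i libraries. MCM3 (0.79) passed over all genes, and 3 members, MCM3, RRM1 (0.59) and RRM2 (1.06), when adjusted over the list alone. In the technical list of replication-dependent histones, 8 of 28 members were measured, and all 8 were positive (median 1.05, camera adjusted p = 1.07e-05). For this list the camera adjusted p was 0.501 with an estimated correlation, and the fry adjusted p was 0.0464. HIST1H1C (1.08) and HIST1H4C (1.22) rose over all genes, and 4 members, with HIST1H2BD (0.97) and HIST1H2BK (1.03), when adjusted over the list alone. Histone genes share sequence, so reads could have been split among copies.

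Heat shock, cholesterol and immediate early genes were also called higher with p38i. Of 12 heat shock genes 11 were positive (median 0.52, camera adjusted p = 1.63e-05; adjusted p = 0.36 with an estimated correlation; fry adjusted p = 0.0253). The chaperone gene HSPH1 (0.99) and HSPA1A (1.34) rose over all genes. With DNAJB1 (0.83), DNAJA1 (0.55) and HSPA1B (1.21, named after its value was seen), 5 passed when adjusted over the list alone. HSPA1A and HSPA1B are near-identical, so their split is uncertain. All 20 cholesterol synthesis genes were positive (median 0.56, camera adjusted p = 8.13e-06; adjusted p = 0.684 with an estimated correlation). None passed over all genes and 4 did when adjusted over the list alone, STARD4 (1.14) and HMGCS1 (0.59) among them. Of 17 immediate early genes 14 were positive (median 0.58, camera adjusted p = 0.000414; adjusted p = 0.542 with an estimated correlation). Their median log2 CPM was 4.97, 5.75 and 6.49 in control 1-1, 1-3 and 2-1, and 6.12, 5.41 and 6.49 in p38i 3-3, col5 and col6. None passed over all genes, and 3, IER2 (0.82), FOSL2 (1.02) and JUND (0.52), passed when adjusted over the list alone.

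Epithelial genes and ribosomal protein genes were called lower with p38i. Of 15 epithelial genes 13 were negative, with a median of -0.57 (camera adjusted p = 0.0195; adjusted p = 0.762 with an estimated correlation). Control 2-1, with a median log2 CPM of 5.51, lay within the p38i libraries (5.1 to 5.79). No member passed over all genes or over the list alone, with CLDN4 at -0.57, MUC1 at -2.07 and ELF3 at -1.88. Of 28 cytosolic ribosomal protein genes 26 were negative, with a median of -0.20 (camera adjusted p = 0.00098; adjusted p = 0.762 with an estimated correlation). None passed over all genes and RPS4X (-1.05) passed when adjusted over the list alone.

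The lists nearest to the drug targets were not called with p38i. The 24 p38 pathway components had a median of -0.11 (camera adjusted p = 0.621) and no member passed. Nor did any of the 14 p38-responsive cytokine and ARE transcripts (median 0.14, camera adjusted p = 0.278), with IER3 at 0.69 and CXCL8 at 0.90. The 14 PRC2 subunits had a median of 0.17 (camera adjusted p = 0.206). Of 26 genes reported as EZH2-repressed (median -0.08, camera adjusted p = 0.861), GATA6 rose by 1.73 and TIMP3 fell by 1.45 over all genes, while 4 passed when adjusted over the list alone, with SLIT2 (-1.71) and DKK1 (1.35). Of 11 breast stem cell associated genes (camera adjusted p = 0.487), CXCR4 rose and ID1 and ID3 fell over all genes, and 5 passed when adjusted over the list alone, SOX2 (-1.07) among them. LOXL2, a collagen cross-linking enzyme, rose by 0.94 among 20 mesenchymal genes (camera adjusted p = 0.679), and FN1, at -1.41, passed only when adjusted over the list alone.

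Other lists were not called with p38i. Camera adjusted p values were 0.613 for invasion proteases (TIMP3 fell, and 4 members passed when adjusted over the list alone, with MMP7 at -3.79), 0.697 for cell cycle inhibitors and p53 targets, 0.518 for apoptosis genes and 0.5 for the type I interferon response and for NF-kB targets. They were 0.613 for antigen presentation, 0.621 for hypoxia (where ANGPTL4 fell by 1.34), 0.697 for the unfolded protein and integrated stress response, 0.75 for the Notch pathway, 0.253 for oxidative phosphorylation and 0.697 for housekeeping genes. Members that passed over the list alone went both ways. Among apoptosis genes 2 were higher and 1, BBC3 (-1.10), lower. Among interferon response genes 3 were higher, IFIH1 (0.84) among them, and 1 lower, and in antigen presentation 1 was higher and 2 lower. Among cell cycle inhibitors and p53 targets, and in the unfolded protein list, 1 was higher each. Among other cell types the camera adjusted p values were 0.632 for fibroblast markers (where PDGFRB, higher in control 1-1 and 1-3 than in 2-1, fell by 2.03), 0.801 for macrophage, 0.18 for endothelial, 0.519 for pericyte and 0.128 for skeletal muscle markers, whose median of 4.03 rested on p38i col6. Too few members were measured to test neutrophil markers, erythroid (HBB 1.55, not past the threshold), adipocyte (median -0.29) and keratinocyte and luminal markers (median 0.19). The file held no mitochondrially encoded gene. For antigen presentation the median was 0.02 but the mean -0.51, and for the Notch pathway 0.01 and -0.21, with camera's direction down for both.

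The p38i count rested on few libraries. It was 2 without p38i 3-3, 7 without col5, 2 without col6, 32 without control 1-1, 3 without 1-3, 568 without 2-1, 446 without EZH2i 5-4, 143 without combination 8-1, 87 without 9-1 and 122 without 9-2. Of the 221 genes, 1, ITGA10, passed with each of the 12 libraries left out. The epithelial call ended without control 1-1 (camera adjusted p = 0.367), control 1-3 (0.103), p38i col5 (0.0727) or col6 (0.0968), and without col6 the hypoxia list was called higher (0.00224). Skeletal muscle markers were called higher without control 1-1 (0.0077), p38i 3-3 (0.000146) or col5 (0.035). They were also called with a mean of at least 5 CPM (0.0226). The groups did not overlap for 24.8% of the genes tested, where chance gives 10%.

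With EZH2 inhibition alone, 11 genes rose and 16 fell, and these were 10 and 8 with library totals alone as the scaling. HSPH1, a heat shock chaperone, rose from 125 ± 11.4 to 320 ± 7.26 CPM (mean ± SD, n = 3), by 1.36 on the log2 scale (SE 0.158, edgeR adjusted p = 0.00224). ITGA10 fell from 267 ± 42.6 to 84.6 ± 16.5 CPM, by 1.66 (SE 0.188, edgeR adjusted p = 0.00224). FKBP5, a co-chaperone of steroid receptors, fell from 140 ± 54.1 to 21.8 ± 7.56 CPM, and METTL7A from 51.7 ± 14.8 to 15.7 ± 4.55 CPM. CXCR4 rose from 64.5 ± 4.35 to 202 ± 29.7 CPM and ADTRP from 50.7 ± 19.1 to 179 ± 72.8 CPM.

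Other genes that rose with EZH2i were HSPA1A (3.34-fold), the LIM protein gene CSRP2 (3.03-fold), the zinc finger gene ZNF521 (2.59-fold) and the secreted protease gene ADAMTS6 (2.49-fold). The sialyltransferase gene ST3GAL6 rose 2.43-fold, the inositol transporter gene SLC5A3 2.17-fold, SRPX 1.92-fold and the kinase gene SGK1 1.78-fold. Genes that fell included LGALS9, which encodes galectin 9 (9.12 ± 4.46 CPM in control and 0.936 ± 0.756 in EZH2i tumours), FKBP5 (6.44-fold lower) and METTL7A (3.31-fold lower). C19orf18 fell by 1.56, the lectin gene CLEC2D by 1.54, SLC37A2 by 1.49, FAM155A by 1.42 and SMAD6, an inhibitory SMAD, by 1.31 on the log2 scale. The ciliary gene CC2D2A fell by 1.29 and C9orf89 by 0.97. Apart from HSPH1 and ITGA10, the edgeR adjusted p values of the named genes lay between 0.0166 and 0.0487. As the rule for naming demands, the 3 EZH2i libraries lay apart from the 3 controls in each.

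Called lists with EZH2i again included proliferation and heat shock genes. All 23 G2/M genes were positive (median 0.54, camera adjusted p = 5.38e-07; adjusted p = 0.855 with an estimated correlation), and 0 passed over all genes and 6 when adjusted over the list alone, CCNB2 (0.98) and TPX2 (0.78) among them. Of 20 S phase and E2F genes 19 were positive (median 0.36, camera adjusted p = 5.93e-05; adjusted p = 0.855 with an estimated correlation), with 4 past the threshold over the list alone, such as MCM3 (0.59) and CDC6 (0.84). Control 2-1 lay near the EZH2i libraries for both lists, with a median log2 CPM of 6.44 against 6 to 6.84 for G2/M genes and 4.97 against 4.98 to 5.18 for S phase genes. Control 1-1 and 1-3 thus carried most of the difference. Of 12 heat shock genes 10 were positive (median 0.51, camera adjusted p = 4.33e-06; adjusted p = 0.23 with an estimated correlation; fry adjusted p = 0.0113). HSPH1 and HSPA1A rose over all genes, and 7 members, with DNAJB1 (1.00) and HSPA1B (1.74), when adjusted over the list alone. The 8 histone genes were positive (median 0.71, camera adjusted p = 0.00248; adjusted p = 0.855 with an estimated correlation), and HIST1H1C (0.72) passed over the list alone.

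Metabolic, stimulus and hypoxia lists were called higher with EZH2i, each with an adjusted p of 0.855 under an estimated correlation. Immediate early genes had a median of 0.28 (camera adjusted p = 0.00559), and EGR1 (0.77) and FOSL2 (1.12) passed when adjusted over the list alone. Control 2-1 (median log2 CPM 6.49) lay above the 3 EZH2i libraries (5.81 to 6.22), so the rise rested on control 1-1 (4.97) and 1-3 (5.75). Cholesterol synthesis genes had a median of 0.33 (camera adjusted p = 0.00776), and STARD4 (1.22) passed over the list alone. Control 2-1 lay within the EZH2i libraries for cholesterol genes (5.47 against 5.26 to 6.08), as it did for histone genes (3.51 against 3.49 to 3.71). Of 23 hypoxia genes 21 were positive (median 0.28, camera adjusted p = 0.00776). Over the list alone, SLC2A1 (0.68), which encodes a glucose transporter, and ERO1L (0.67) rose and ANGPTL4 (-1.08) fell. Epithelial genes were called lower (median -0.82, 13 of 15 negative, camera adjusted p = 0.00776; adjusted p = 0.855 with an estimated correlation). Over the list alone 3 members passed, EPCAM (-1.21) and KRT8 (-0.67) among them. Ribosomal protein genes were called lower (median -0.15, camera adjusted p = 0.0395; adjusted p = 0.939 with an estimated correlation).

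Genes reported as EZH2-repressed were not called as a list with EZH2i (median -0.12, camera adjusted p = 0.978), and 0 of the 26 passed over all genes. Over the list alone, 5 did. GATA6 (1.68), NKX2-5 and DKK1 (1.35, named after its value was seen) were higher, and TIMP3 (-1.06) and SLIT2 (-1.81) were lower. NKX2-5 measured 4.51 ± 1.38 CPM in EZH2i tumours and 0.179 ± 0.158 in controls, where counts were near 0. PRC2 subunits had a median of 0.24 (camera adjusted p = 0.397), with RBBP4 at -0.64. Mesenchymal genes were not called by camera (adjusted p = 0.425) but were by fry (adjusted p = 0.035), with MMP2 (11 ± 9.62 CPM against 0.797 ± 0.61), LOXL2 (0.67) and CD44 (0.67) past the threshold over the list alone. Breast stem cell associated genes (camera adjusted p = 0.958) went both ways. CXCR4 rose over all genes, and over the list alone 2 members, CXCR4 and CD44 (0.67), were higher and 3 lower, ID1 (-1.81) and ID3 (-1.96) among them. Among invasion proteases 3 members were higher over the list alone and 2 lower, among apoptosis genes 2 were higher and 1 lower, and 1 member each of the p38-responsive and endothelial lists was higher. No other tested list was called with EZH2i, and their camera adjusted p values lay between 0.199 for the p38-responsive transcripts and 0.975.

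Leaving out most single libraries moved the EZH2i count of 27. It was 7 without control 1-1, 4 without 1-3, 125 without 2-1, 10 without p38i 3-3, 6 without col5, 55 without EZH2i 5-3, 2 without 5-4, 2 without 6-1, 11 without combination 8-1, 6 without 9-1 and 6 without 9-2. HSPH1 and ITGA10 passed with each of the 12 libraries left out. List calls numbered 9, and 5 without control 1-1 or without 1-3. Without 1-1 the epithelial (camera adjusted p = 0.306), immediate early (0.114), cholesterol (0.234) and ribosomal (0.0688) calls ended, and without 1-3 the epithelial, immediate early, hypoxia and ribosomal calls (each 0.0511). Without EZH2i 6-1 the epithelial and immediate early calls (each 0.0764) and the ribosomal call (0.642) ended, without 5-4 the cholesterol (0.41) and ribosomal (0.401) calls, and without 5-3 the hypoxia call (0.498). The ribosomal call ended in 10 of the 12 cases, its adjusted p being at most 0.642, and with library totals alone (0.061). It held only without EZH2i 5-3 and without p38i 3-3. The groups did not overlap for 16.4% of genes, where chance gives 10%.

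**Figure D2:**
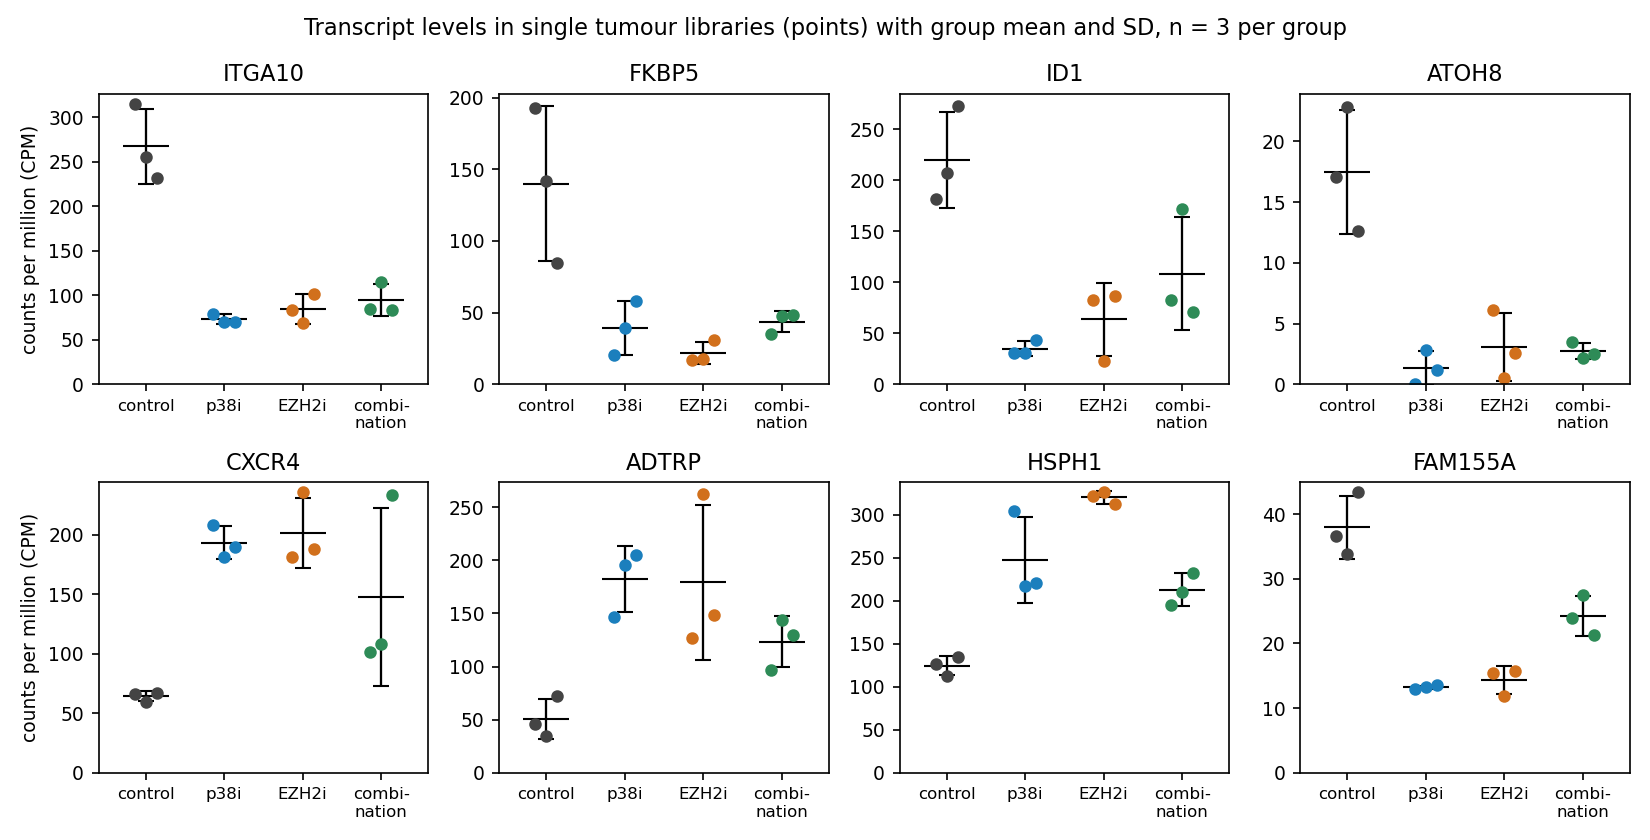
CPM of 8 genes (vertical axes, each from 0) in the 12 libraries, 1 point per library, by treatment group, with the group mean and SD (n = 3). ITGA10 lies at 267 ± 42.6 CPM in control and 73.1 ± 5.5, 84.6 ± 16.5 and 94.5 ± 18.1 CPM in p38i, EZH2i and combination tumours.

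With both inhibitors together, 1 gene passed. ITGA10 fell from 267 ± 42.6 to 94.5 ± 18.1 CPM (mean ± SD, n = 3), which is 2.82-fold lower (SE 0.185 on the log2 scale, edgeR adjusted p = 0.00974). CXCR4, FKBP5, METTL7A and HSPH1, which changed with EZH2i alone, lay on the same side of the control mean in the combination without passing. CXCR4 measured 148 ± 74.5 CPM, FKBP5 43.7 ± 7.43, METTL7A 19.7 ± 0.557 and HSPH1 213 ± 19.2 CPM. Unadjusted p values below 0.05 numbered 2043, where 626 would come by chance, and the groups did not overlap for 22% of genes, where chance gives 10%.

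Lists called higher in the combination included proliferation genes. All 23 G2/M genes were positive (median 0.61, camera adjusted p = 3.18e-08; adjusted p = 0.631 with an estimated correlation), and 8 passed when adjusted over the list alone, with CCNB2 (0.96), CCNA2 (0.98), BUB1 (0.95) and CDK1 (0.79). S phase and E2F genes (median 0.44, camera adjusted p = 2.99e-05), cholesterol synthesis genes (median 0.44, camera adjusted p = 0.000547) and histone genes (median 0.45, camera adjusted p = 0.0165) had no member past the threshold, and each had an adjusted p of 0.631 with an estimated correlation. Immediate early genes had a median of 0.70 (camera adjusted p = 0.000263; adjusted p = 0.613 with an estimated correlation), and EGR1 (0.90) passed when adjusted over the list alone. All 12 heat shock genes were positive (median 0.29, camera adjusted p = 0.00223; adjusted p = 0.613 with an estimated correlation). Control 2-1 lay within the combination libraries in median log2 CPM for immediate early (6.49 against 6.14 to 6.58), heat shock (7.24 against 7.2 to 7.51) and histone genes (3.51 against 3.4 to 4.14). Of the heat shock genes, HSPH1 (0.77), HSPA1A (1.17), HSPA1B (1.25) and DNAJA1 (0.50) passed when adjusted over the list alone.

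Inflammatory gene lists were called higher in the combination. Of 18 NF-kB targets 16 were positive (median 0.58, camera adjusted p = 0.00112; adjusted p = 0.631 with an estimated correlation), and NFKB1 (0.63) and CXCL8 (1.45), which encodes interleukin 8, passed when adjusted over the list alone. All 14 p38-responsive cytokine and ARE transcripts were positive (median 0.67, camera adjusted p = 0.00153; adjusted p = 0.613 with an estimated correlation). CXCL8 passed over the list alone, IL11 stood at 1.56 and CXCL2 at 1.13. Both lists as written hold CXCL8, CXCL1, CXCL2, IL6, CCL20, TNFAIP3, NFKBIA, BIRC3 and ICAM1, so their calls are not independent. Hypoxia genes had a median of 0.32 (camera adjusted p = 0.0152; adjusted p = 0.709 with an estimated correlation), with SLC2A1 (0.68), VEGFA (1.22) and ERO1L (0.70) past the threshold over the list alone. Ribosomal protein genes were called lower (median -0.21, camera adjusted p = 0.00294; adjusted p = 0.643 with an estimated correlation).

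Mesenchymal genes were called by fry in the combination (adjusted p = 0.00568) and not by camera (adjusted p = 0.17). Their members LOXL2 (0.72), CD44 (0.71), SNAI2 (0.78) and LOX (0.97) passed when adjusted over the list alone. Epithelial genes had a median of -0.30 (camera adjusted p = 0.232). Of the genes reported as EZH2-repressed (median -0.02, and 0.05 with library totals alone; camera adjusted p = 0.591), DKK1 (1.90), GATA6 (1.51) and NKX2-5 (2.81 ± 2.2 CPM) passed over the list alone. The other tested lists had camera adjusted p values between 0.154 and 0.77. A further 2 breast stem cell associated genes were higher over the list alone and 1 apoptosis gene lower. Fibroblast markers had a median of 0.34 and a mean of -0.29, and breast stem cell associated genes 0.20 and -0.06.

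In the combination, the count of 1 was 0 without control 1-1, without 1-3 or without combination 9-2, 229 without control 2-1, 7 without EZH2i 5-3, 32 without 5-4 and 3 without combination 8-1. The hypoxia call ended without control 2-1 (camera adjusted p = 0.0674) and the histone call without combination 8-1 (0.455), while the epithelial list was called lower without control 2-1 (0.00353).

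**Figure D3:**
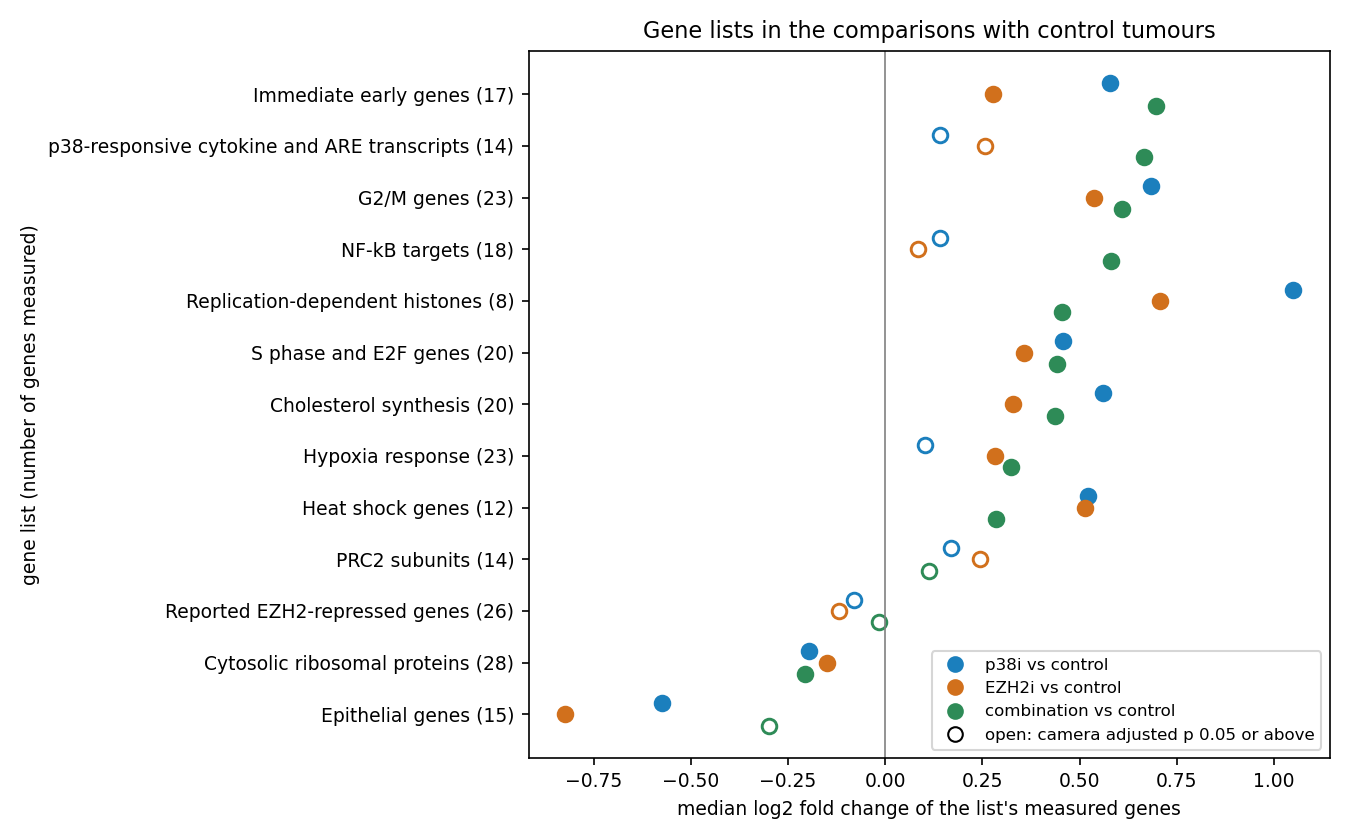
Median log2 fold change (horizontal axis) of the measured members of 13 gene lists in the 3 comparisons with control, 1 point per list and comparison. Filled points are lists with a camera adjusted p below 0.05 at the preset correlation, none of which kept its call with an estimated one, and G2/M genes lie at 0.68, 0.54 and 0.61.

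The combination was set against p38i alone to ask what EZH2 inhibition adds. edgeR called 0 genes, with 977 unadjusted p values below 0.05, where 626 would come by chance, while limma-voom called 0 and DESeq2 3. The smallest p values belonged to genes that did not pass (edgeR adjusted p from 0.407 to 0.575). SERPINA3 measured 11.7 ± 1.96 CPM in combination and 2.03 ± 0.603 in p38i tumours, PTX3, a soluble pattern recognition molecule, 71.6 ± 33.6 and 17.3 ± 4.05, and GLI2, a transcription factor of Hedgehog signalling, 9.34 ± 1.11 and 3.10 ± 0.907. FAM155A (log2 0.88) and SLITRK6 (2.66) also lay higher. PFDN6 (2.01-fold lower), NARS (-0.77), CCDC69 (-1.42), SRF (-0.98) and SLC39A4 (-1.58) lay lower.

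Against p38i alone, camera called NF-kB targets higher in the combination (median 0.34, 14 of 18 positive, adjusted p = 0.0059; adjusted p = 0.501 with an estimated correlation). It called histone genes lower (median -0.52, adjusted p = 0.0059; adjusted p = 0.501 with an estimated correlation), and HIST1H1C (-0.71) and HIST1H4C (-0.81) passed when adjusted over the list alone. Hypoxia genes were called higher (median 0.12, adjusted p = 0.044; adjusted p = 0.76 with an estimated correlation). Skeletal muscle markers were called lower (median -6.19, adjusted p = 0.00527; adjusted p = 0.501 with an estimated correlation), with all 5 measured members lower over the list alone, and 11 of 12 markers highest in p38i col6. The p38-responsive cytokine and ARE transcripts were not called (median 0.341, 11 of 14 positive, camera adjusted p = 0.0594), but were called higher with the host covariate (0.0124) and without control 1-3, p38i 3-3, EZH2i 5-3, EZH2i 6-1 or combination 8-1 (at most 0.0463). A breast stem cell associated gene was higher over the list alone, and 2 apoptosis genes and 1 endothelial marker were lower. Without p38i col6, 0 lists were called, with adjusted p values of 0.0967 for NF-kB targets and muscle markers and 0.0919 for histone genes, and the hypoxia list turned to lower (0.708). Without p38i col5, 2 were called, and NF-kB targets (0.157) were not. Without p38i 3-3, 7 were called. The histone call also ended without combination 9-1 (0.184), and the hypoxia call in 8 of the 12 cases, with adjusted p values from 0.0514 upward, holding without control 1-3, p38i 3-3, EZH2i 5-3 and 6-1. The groups did not overlap for 15% of genes, where chance gives 10%.

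Set against EZH2i alone, which asks what p38 inhibition adds, the combination showed 0 genes past the threshold in edgeR. Unadjusted p values below 0.05 numbered 391, fewer than the 626 expected by chance, and DESeq2 and limma-voom called 0. Among genes that did not pass (each with an edgeR adjusted p of 0.991), PTX3 measured 71.6 ± 33.6 CPM in combination and 18.8 ± 5.71 in EZH2i tumours. F3, which encodes tissue factor, measured 328 ± 101 and 112 ± 38.1, and SNAI2, a mesenchymal transcription factor gene, 56 ± 3.98 and 33.4 ± 7.32. FAM155A (log2 0.77) and FASTKD3 (1.76) lay higher, and UGT2B7 (-1.60), CCDC112 (-0.67), HSPH1 (-0.59), HSPB1 (-0.89) and TMEM160 (-1.38) lower.

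Camera called NF-kB targets higher in the combination than with EZH2i (median 0.29, 16 of 18 positive, adjusted p = 0.00207; adjusted p = 0.884 with an estimated correlation). Heat shock genes were called lower (median -0.28, 9 of 12 negative, adjusted p = 0.02; adjusted p = 0.871 with an estimated correlation), and HSPH1, HSPB1 and DNAJB1 (-0.67) passed when adjusted over the list alone. The p38-responsive transcripts, the list nearest to the agent added, were not called (median 0.313, 12 of 14 positive, camera adjusted p = 0.0688; adjusted p = 0.884 with an estimated correlation). They were called higher with the host covariate (0.00989) and without control 1-3, p38i 3-3, col5, col6, EZH2i 5-3 or combination 8-1 (at most 0.0242). The heat shock call ended with the host-cell covariate (adjusted p = 0.0615), without EZH2i 6-1 (0.339) and without combination 8-1 (0.0828), and the NF-kB call ended without EZH2i 6-1 (0.48). List calls numbered 2, but 0 without EZH2i 6-1 and 5 without 5-3, without 5-4 or without combination 9-2. The groups did not overlap for 7.11% of genes, where chance gives 10%.

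The interaction asks whether the change with one inhibitor depends on the other, and 3 genes passed. ITGA10 had an interaction of 2.04 (log2, SE 0.263, edgeR adjusted p = 0.00815), having fallen by 1.87 with p38i, by 1.66 with EZH2i and no further with both. FAM155A, which encodes a subunit of the sodium leak channel complex, had an interaction of 2.30 (SE 0.283, edgeR adjusted p = 0.00815). It fell by 1.52 and 1.42 with the single agents and stood at -0.64 in the combination, with 38 ± 4.87 CPM in control and 24.3 ± 3.1 in combination tumours. HSPH1 had an interaction of -1.58 (SE 0.221, edgeR adjusted p = 0.0142), having risen by 0.99 and 1.36 with the single agents, and stood at 0.77 in the combination. By the arithmetic of this contrast, a gene shifted equally in all 3 treated groups has an interaction of that size with the opposite sign. ITGA10 and FAM155A passed with each of the 12 libraries left out, and HSPH1 with 9, its adjusted p being 0.112 without control 1-3, 0.0532 without combination 8-1 and 0.0822 without 9-1.

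As lists, G2/M genes (median interaction -0.66, camera adjusted p = 6.47e-06), S phase and E2F genes (-0.46, 0.00311), cholesterol synthesis genes (-0.43, 0.00352), histone genes (-1.22, 3.29e-05) and heat shock genes (-0.68, 6.47e-06) had a negative interaction. Epithelial genes had a positive one (1.23, camera adjusted p = 0.00423). With an estimated correlation the adjusted p was 0.603 for histone genes, 0.22 for heat shock genes and 0.715 for the other 4 lists, and fry called heat shock genes (adjusted p = 0.0199). Over the list alone, 6 heat shock genes passed, DNAJB1 (-1.50), HSPA1A (-1.91) and HSPB1 (-1.39) among them, and 4 histone genes. ID1 (3.45), ID3 (3.29) and CXCR4 (-2.04) passed among the breast stem cell associated genes when adjusted over the list alone. The count of 3 genes was 7 without control 1-1, 12 without 2-1, 8 without p38i col6 and 42 without EZH2i 5-3, and the epithelial (camera adjusted p = 0.116), S phase (0.125) and cholesterol (0.0909) calls ended without control 1-1, and the cholesterol call also without EZH2i 5-4 (0.108).

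The single agents were compared through the genes called with each, and not with each other directly. Of the 27 genes called with EZH2i, 23 were also called with p38i, 9 higher and 14 lower in both and 0 in opposite directions. Of the 221 genes called with p38i, 198 were not called with EZH2i. The remaining 4, H6PD, LGALS9, SLC5A3 and SGK1, had p38i log2 fold changes of -0.40, -1.36, 0.75 and 0.43 that did not pass. Independent lists of these sizes would share 0.0721 genes upward and 0.178 downward. Simulated unchanged groups, set against simulated controls that they shared, had 0.0333 shared calls on average and 1 at most. With no gene changed such groups give few calls, so this says little about the 23 shared genes. The shared count was 6 without control 1-1, 2 without 1-3 and 101 without 2-1. ITGA10 was the 1 gene that the combination shared with either agent. Those shared counts were 0 without control 1-1 or 1-3, and 155 with p38i and 70 with EZH2i without 2-1.

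Across genes, which are not independent replicates, log2 fold changes against control correlated at 0.777 (Pearson) between p38i and EZH2i, 0.697 between p38i and the combination and 0.773 between EZH2i and the combination. Simulated unchanged groups that shared simulated controls, all drawn from the same mean for each gene, gave 0.5, 0.507 and 0.498. Covariances were 0.228, 0.196 and 0.215, against simulated values of 0.0689, 0.0683 and 0.0683, which leaves differences of 0.159, 0.128 and 0.147. The 3 controls could not be split into 2 sets of at least 2 libraries, so part of the excess may come from the shared controls, of which 1-1 and 1-3 stood apart on component 1. Under the scalings tried, the median log2 fold change of all genes lay within 0.0671 of 0, and none of the called lists named here changed the sign of its median.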

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

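Of the fits in this part, those with offsets for GC content and length and without the columns col5 and col6 were chosen only after the result was seen, and the regroupings of libraries were chosen before.

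The results below are differences of differences, in which the change with p38i was not the same with and without EZH2i. On the log2 scale the interaction was 2.04 for ITGA10, 2.30 for FAM155A and -1.58 for HSPH1, and the 3 genes were called by edgeR with all 12 libraries. By the arithmetic of the contrast, a gene that shifts by the same amount in all 3 treated groups gets an interaction of that size with the opposite sign. ITGA10 stood at -1.87 with p38i and -1.66 with EZH2i against control, with 0.37 between the combination and p38i and 0.17 between the combination and EZH2i. For these genes the interaction therefore records that the combination did not add the 2 single changes. The GC and length offsets gave 6 genes, and leaving out col5 and col6, which leaves 1 p38i library, gave 1.

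As lists, heat shock genes (camera adjusted p = 6.47e-06), G2/M genes (6.47e-06), replication-dependent histones (3.29e-05), S phase and E2F genes (0.00311) and cholesterol synthesis genes (0.00352) had a negative interaction, and epithelial genes (0.00423) a positive one. With an estimated correlation all 6 calls were lost, at adjusted p values of 0.22 for heat shock genes, 0.603 for histones and 0.715 for the other 4 lists. Against control these lists had medians of the same sign in each treated group, positive for the first 5 and negative for the epithelial genes.

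Among 100 regroupings of the 12 libraries into 4 groups of 3, the real one included, 3 gave at least the 3 genes of the real groups. That share is under 0.05 but does not exclude chance, since it needs exchangeable libraries. Libraries with the same leading title number had a consensus correlation of 0.179. Of the 3 regroupings, the 2 other than the real one gave 521 and 108 genes, many times the real count. They may reflect a structure of the samples that the groups do not follow, which was not tested. For the lists, 58 of the 100 regroupings gave at least the 6 lists called in the real groups, with 15 in the highest other, so chance is not excluded there. No biological explanation was tested for the interaction.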

How the results depend on the processing

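The contrast of the mean of the treated groups, the GC and length offsets and the fits without pairs of libraries were chosen only after the data were seen.

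DESeq2 called 617 genes for p38i, 227 for EZH2i, 151 for the combination, 3 for the combination against p38i, 218 for the interaction and 827 for the mean of the treated groups, and its shared calls numbered 172 (p38i and EZH2i), 92 (p38i and combination) and 86 (EZH2i and combination). On simulated counts it made 16 false calls of 135 against 5 of 114 with edgeR. Without a filter the counts were 114 for EZH2i, 42 for the combination, 1 for the combination against p38i and 70 for the interaction. limma-voom gave 16 for EZH2i, and with the leading title number as a random effect 53 for p38i, 2 for EZH2i and 93 for the mean of the treated groups (a fit added later than the others). The host covariate gave 120, 6, 3 and 257 for p38i, EZH2i, the combination and the mean of the treated groups. Fits of only the compared groups gave 4 for EZH2i and 4 for the combination, library totals alone 3 for the combination, and a 2-fold minimum 135 for p38i. GC and length offsets gave 6 for the interaction. Except for the 2-fold minimum, which adds a demand, the cause was not tested.

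Leaving out col5 and col6 gave 0 genes for p38i (846 at an unadjusted p under 0.05 in edgeR), 7 for EZH2i and 1 for the interaction. Leaving out control 1-1 and 1-3 gave 7 for p38i, 0 for EZH2i (860 unadjusted) and 0 for the combination (419 unadjusted). Each leaves 1 library in a group, which is assumed to vary like the others. No other tool was run without these pairs.

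With an estimated correlation camera called 0 lists in each of the 6 comparisons. fry called 2 lists for p38i, 2 for EZH2i, 1 for the combination, 0 and 0 for the combination against p38i and EZH2i, and 1 for the interaction.

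With each library left out in turn, genes called ran from 2 to 568 for p38i, 2 to 125 for EZH2i, 0 to 229 for the combination, 0 to 0 for each comparison with a single agent, 2 to 42 for the interaction and 12 to 911 for the mean of the treated groups. Camera called 7 to 9, 5 to 9, 9 to 10, 0 to 7 (combination against p38i), 0 to 5 (against EZH2i) and 4 to 9 lists. With each of the 3 controls left out, shared calls ran from 2 to 101, 0 to 155 and 0 to 70, and correlations of fold changes from 0.754 to 0.844, 0.653 to 0.805 and 0.737 to 0.853, in the order of the shared calls above. Counts fell without control 1-1 or 1-3 and rose without 2-1 in the 3 comparisons with control.

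For the named genes, no sign changed where the gene passed in the main fit or in the alternative. Changes of sign where it passed in neither were counted as unchanged. With a library left out 9278 values stayed on their side of the threshold, 93 newly passed and 397 no longer did. Under the other alternatives these were 8203, 138 and 158. The values that stayed include those of genes that passed in neither fit. Of 180 list medians, 12 changed sign with the scaling, none of them of a called list. Over the fits with another scaling, filter or host covariate and with a library left out, 48 list calls were lost and 51 gained. These counts leave out fry and camera with an estimated correlation, which called 0 lists in each comparison. The hypoxia list, called higher in the combination against p38i, turned to lower without col6 (camera adjusted p = 0.708). No paired analysis was possible because the leading numbers of the tumour titles are never shared between groups. The simulated recovery was 0% for changes of 0.5 and 50% for changes of 1 on the log2 scale. It covers genes with a mean of at least 5 CPM and limits what the counts of calls can show.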

Other observations

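The contrast of the mean of the 3 treated groups with the control was chosen after the data were seen. So were its fit with the title number as a random effect and the tests of the control 2-1 share, of host cells on that contrast, of host markers, of the lists under regrouping, and of the BMP-SMAD and glucocorticoid lists, which were also written then.

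Against the mean of the 3 treated groups, 386 genes differed from control, 127 higher and 259 lower (edgeR, 2698 at an unadjusted p under 0.05), and 173 and 187 with library totals alone. CXCR4 measured 64.5 ± 4.35 CPM in the 3 controls and 181 ± 47.8 in the 9 treated libraries, and ADTRP 50.7 ± 19.1 and 162 ± 50.4. The lymphangiogenic factor gene CCBE1 was 3.74-fold higher, ATP6V0D2 3.39-fold, the retinoic acid hydroxylase gene CYP26B1 3.29-fold, GATA6 3.12-fold, the heat shock gene HSPA6 2.85-fold and ACVR1C, a type I activin receptor gene, 2.72-fold. ATOH8 was 7.78-fold lower, PAPLN 6.99-fold, IFITM10 5.95-fold, LGALS9 4.8-fold and SNED1 4.65-fold. FKBP5 fell from 140 ± 54.1 to 35 ± 14.7 CPM and the epithelial sodium channel gene SCNN1A from 238 ± 74.9 to 61.6 ± 27.2 CPM. The named genes were chosen among those in which the 3 controls lay apart from the 9 treated libraries. Such separation held for 6.12% of genes, where chance gives 0.909%. The count was 35 without control 1-1, 12 without 1-3, 911 without 2-1, 211 without p38i 3-3, 212 without col5, 231 without col6, 597 without EZH2i 5-3, 149 without combination 9-1 and 120 without 9-2.

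Camera called 10 lists in this contrast, 0 with an estimated correlation, and fry 2, heat shock and mesenchymal genes (each adjusted p = 0.00898). G2/M genes had a median of 0.63 (camera adjusted p = 1.11e-09), immediate early genes 0.50 and p38-responsive transcripts 0.29 (camera adjusted p = 0.0342). Of 100 regroupings into 4 groups of 3 libraries, 1, the real one, gave as many as 386 genes, and the highest other gave 39. This would exclude chance only for exchangeable libraries and a contrast chosen beforehand, and this contrast was chosen after the data were seen. The regroupings break up libraries that share a leading title number, whose consensus correlation was 0.179. With that number as a random effect, limma-voom called 93 genes, against 307 without it. For the lists 11 of 100 gave at least 10, with 13 in the highest other, so chance is not excluded there.

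The treated libraries were thus shifted together against the controls. A candidate explanation is that control 1-1 and 1-3 stand apart. Of the 911 genes called without control 2-1, 887 were also tested with all 12 libraries. For these, control 2-1 showed a median share of 0.333 of the shift (interquartile range 0.086 to 0.569). In it 725 of the 887 (81.7%) lay on the same side of the treated mean as in the other controls. Left out in turn, control 1-1 showed a median share of 0.882 (35 genes) and 1-3 of 0.998 (12 genes). The 887 genes were picked for their shift in 1-1 and 1-3, so it stays open whether the treated groups or these controls moved. GC content or length trends are argued against as the whole cause, since 343 of 363 called genes (94.5%) stayed called with offsets for both. The host covariate could not test the amount of host cells, which stays open. Its mean was -0.00156 in controls and 0.000521 in treated libraries, a difference of 0.00209 (SE 0.142), so the median size of the change (0.916 without and 0.919 with it, 100%) could hardly move. The covariate kept 248 of the 386 calls, at a median SE of 0.196 before and 0.199 after. The share of MALAT1 (3.12 to 3.88% in controls and 1.47 to 2.82% in treated libraries) and that of the 10 most abundant genes (7.33 to 8.64% and 4.81 to 7.29%) also set the controls apart. A difference in RNA quality was not tested and stays open. The leading title numbers differ between the groups, so a batch of tumours and the treatment cannot be told apart.

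ID1, ID3, SMAD6 and ATOH8, which respond to BMP through SMAD proteins, were lower in the mean of the treated groups. All 4 passed with p38i. With EZH2i SMAD6 passed (edgeR adjusted p = 0.0411), while ID1 (0.128), ID3 (0.137) and ATOH8 (0.124) did not. With the combination none passed, at edgeR adjusted p values of 0.287, 0.249, 0.18 and 0.165 in the order above. Lower BMP-SMAD signalling is a candidate source of the 4 falls. In the same contrast, the other 7 measured members of a BMP-SMAD list had a median of -0.33 and a fry p of 0.0232. For them camera with an estimated correlation gave a p of 0.129. With p38i the same members had a median of -0.681 and a fry p of 0.0107, though camera with an estimated correlation gave 0.0718. With EZH2i they had a median of -0.135 and a fry p of 0.155, and with the combination -0.292 and a fry p of 0.0764. Whether the groups differ in this was not tested. Among these 7 members, in the mean of the treated groups, SMAD9 stood at -1.21 and was the 1 that passed (edgeR adjusted p = 0.0262). SMAD9 was also called with p38i (edgeR adjusted p = 0.0493). The list was written after such calls, so the 7 members give no independent support. NOG, an antagonist of BMP, stood at 1.43 (edgeR adjusted p = 0.0845). Fewer macrophages and endothelial cells stay open. The lowest of their 13 markers stood at -0.648 (PECAM1, SE 0.315), above the median of -1.9 of the 4 genes. Reads were aligned to a human genome, so mouse host cells could be counted only where their reads aligned to human genes. How far these markers follow the amount of host cells is unknown, so they decide nothing. Fibroblasts stay open, since their 14 markers went both ways, down to -3.69 (MGP, SE 0.757), although their median was 0.116 (quartiles -0.902 and 0.642, 6 of 14 negative) where fewer fibroblasts would need about -1.9. PECAM1 and MGP were named after their values were seen. The host covariate, equal between the groups, left 99.7% of the change and decides nothing. Control 2-1 showed shares of 1.28 (ID1), 0.732 (ID3), 0.705 (SMAD6) and 0.795 (ATOH8) of the shift, and in all 4 genes the 3 controls lay apart from the 9 treated libraries. This goes against control 1-1 and 1-3 as the sole source. It rests on 1 library and on genes named because the groups did not overlap, so it excludes nothing. Lower BMP-SMAD signalling stays a hypothesis, since the list was written after these genes were seen.

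FKBP5, METTL7A and SCNN1A, which glucocorticoids induce, were lower in the mean of the treated groups as well. All 3 passed with p38i. With EZH2i FKBP5 and METTL7A passed (edgeR adjusted p = 0.0223 each) and SCNN1A did not (0.105). With the combination none passed, at edgeR adjusted p values of 0.133, 0.0824 and 0.174. Whether the 3 falls reflect a lower glucocorticoid response stays open, since the other 16 measured members of a list had a fry p of 0.193. With p38i they had a median of -0.321 and a fry p of 0.0464 (0.118 by camera with an estimated correlation). With EZH2i these were -0.202 and 0.207, and with the combination 0.0727, the other way, and 0.815. TSC22D3 (-1.50), KLF9 (-1.56) and ANGPTL4 (-1.09) were lower, while SGK1 (0.68) was higher. Fewer macrophages and endothelial cells stay open here too, since the same markers (lowest -0.648, against a median of -1.98 of the 3 genes) decide nothing. Fibroblasts (lowest marker -3.69, median 0.116) stay open, and the host covariate, which left 99.8% of the change, decides nothing.

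Each pair of groups has only 10 splits of its 6 libraries, too few for a share under 0.05. For p38i 1 of 10 gave as many genes as the real split (221, highest other 2) and 7 as many lists (8, highest other 13). For EZH2i these were 1 (27, highest other 0) and 2 (9, highest other 10), and for the combination 1 (1, highest other 0) and 1 (10, highest other 8). For the combination against p38i they were 10 (0 genes, highest other 0) and 7 (4 lists, highest other 11), and against EZH2i 10 (0 genes, highest other 0) and 8 (2 lists, highest other 10).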
